A study of Mus musculus with 4 samples.

How the data were processed

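DNA methylation was measured by whole-genome bisulfite sequencing of mouse germline stem cells after about 5 or 60 months of culture, with 2 replicates per age. Libraries were made by post-bisulfite adaptor tagging, per the labels' protocols. Reads were aligned to mm10 with Bismark 0.10.0, per the submitters' processing notes. The deposited tables give for each CpG the count of methylated calls and the count of unmethylated calls, made from the aligned reads by the authors without further normalization. They also give the percent of methylated calls, computed by the authors from these counts. One table was deposited per culture age and named for both of its replicates, and it holds no replicate column, so replicates were pooled before deposit. Filters, deduplication and merging of strands are not given in the sources used here. Chromosomes 1 to 19 and X were used, and chromosome Y was not analysed here.

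Everything below was computed from the methylated and unmethylated counts, and the percent column served only to check them. The level of a region is the percent of methylated calls among all calls on its CpGs with at least 5 calls in both tables. Regions with at least 4 such CpGs were compared by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over all regions of a kind, and called at an adjusted p under 0.05 with a difference of at least 20 percentage points. Single CpGs needed at least 10 calls in both tables. Windows of 100 kb needed at least 100 CpGs and were described by a difference of at least 10 points, without a test. Intervals of levels are 95% Wilson intervals, and those of differences combine 2 Wilson intervals by Newcombe's method. They cover counting error only, since replicates cannot be separated and calls on one read are not independent.

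Genes came from the RefSeq annotation of the same build, which here held no strand, exons or sequence. The 5' end of a gene was therefore taken as the end with at least 2 times the CpGs of the other end within 300 bp on each side, for protein-coding and lncRNA genes of at least 2 kb. This rule was chosen after the tables had been seen, out of 12 settings, by its match to hand-written strands of well-known genes and not by methylation. It was right for 96 (94.1%) of the 102 hand-listed genes with a clear CpG-dense end. The same genes served to choose it, so it may be right less often for other genes. The 12 settings ranged from 82.8% to 98.6%, and the choice traded some accuracy for more genes. In all, 21448 of 34328 protein-coding and lncRNA genes were placed, among them 15043 of 21631 protein-coding genes. Of the 21448, 33 (imprinted, title, Dnmt and Tet genes) were placed by their hand-written strand. A promoter window ran from 1000 bp upstream to 500 bp downstream, at the outermost annotated end, which need not be the main promoter. Gene bodies were replaced by gene spans without 500 bp at each end, since strand was lacking. CpG islands need a genome sequence, which was not used here, and were replaced by CpG-dense clusters: runs of at least 20 CpGs with gaps of at most 50 bp and a length of at least 200 bp. This was the only definition tried at first, set after the genome-wide, tile and single-CpG values had been seen. Exon, UTR and repeat classes were not analysed here.

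Other choices also followed a look at the values: the limit of 1000 calls for CpGs of high depth, the depth ratio limits of 1.08 and 0.92, the 12% limit for imprinted windows, the limits of 10% and 80% for single CpGs that switched, the minimum difference of 50 points and the joining of windows into domains. So did the alternatives with gene spans for lists, both gene ends, a stricter 5' end rule and without chromosomes 15, 16 and 17. The Fisher's exact test, its thresholds, the tile, window and promoter sizes and the gene lists were fixed before the data were examined, as was the rule for naming genes. That rule took the 12 protein-coding promoters with the largest gain and the 12 with the largest loss, without predicted and clone-named genes, up to 4 changed members of each gene list, the title genes, the Dnmt and Tet genes, every imprinted region, and the 5 tiles with the largest gain and the 5 with the largest loss among those with at least 10 CpGs. A few results under this rule are not reported here. Genes and domains named outside it are said to be so or complete a count of 5 or fewer. Gene lists were compared by their median difference with 10000 random lists matched on 5M-GS level and number of CpGs. Imprinted regions were promoter windows of maternally methylated genes, and stretches from 4000 to 2000 bp upstream of H19, 15000 to 11000 bp upstream of Meg3 and 33000 to 29000 bp upstream of Rasgrf1. Of 24 designed regions, 23 were tested.

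The tests were tried on simulated data made from the real regions and depths, with 200 regions changed by known amounts. With independent calls, 1 of 1689849 tiles, 0 of 21076 promoter windows and 0 of 23248 clusters were called falsely. Of 50 promoter windows changed by 25 points all 50 were recovered, and of 50 tiles 45. With all calls of a read identical, false calls numbered 99186 tiles, 691 promoter windows and 335 clusters, nearly balanced between gains and losses. Both simulated libraries shared the same level in each unchanged region, so this balance was set by the design. No difference across a whole library and no spread between replicates was simulated. Dividing the calls of each region by its CpGs, which leaves about the mean depth and fewer observations than there were reads, gave 0, 1 and 0 false calls, but with these identical calls recovered 0 of 50 promoter windows changed by 25 points, 3 of 50 changed by 40 points and 34 of 50 changed by 60 points, so a call it does not make says little. The counts with divided calls are given as a conservative version beside the main ones.

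Alternatives tried were minimum calls of 1 and 10, differences of 10, 30 and 50 points, the mean of per-CpG levels, an upper limit on calls, divided calls, thinning of the deeper table, other tile sizes and promoter windows, a stricter rule for the 5' end, both gene ends, and leaving out chromosomes 15, 16 and 17. The software was Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9.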

Results

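Germline stem (GS) cells are cultures of mouse spermatogonial stem cells, the testis cells that renew themselves and give rise to sperm, kept growing with the factors GDNF and FGF2. The cells came from testis of GFP-transgenic mice on a DBA/2 background and had been in culture for about 5 months (5M-GS) or about 60 months (60M-GS). DNA methylation was measured by whole-genome bisulfite sequencing after post-bisulfite adaptor tagging, a method that adds adaptors after the bisulfite step, for 2 replicates of each culture age. Each age is represented by 1 table in which its 2 replicates are pooled, so no spread between replicates could be measured. Every test below compares the calls of these 2 pooled libraries, not the culture ages as such, and its intervals (95%) cover counting error only. The 5M-GS table held 468121185 methylation calls on 19371838 CpGs, with a median of 21 calls per CpG. The 60M-GS table held 471693518 calls on 19341319 CpGs, with a median of 22. CpGs with at least 5 calls in both tables numbered 17634196, on chromosomes 1 to 19 and X.

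The first comparison asked whether the overall methylation level of the cells differed after the longer culture. The level over all calls was 72.4% in 5M-GS and 76.4% in 60M-GS, a difference of 3.96 points (interval 3.95 to 3.96). Most of this difference came from 842 CpGs with over 1000 calls in at least 1 table, far above the median depth. A single CpG held up to 5138895 calls in 5M-GS. Such positions may collect reads from many copies of a repeat, so their levels need not describe single loci. These CpGs held 7.53% of the 5M-GS calls and 6.89% of the 60M-GS calls, and their level over all calls was 46.8% in 5M-GS and 85% in 60M-GS. The median of these CpGs was 30.2% and 66.1%. Of the 842, 740 were higher in 60M-GS by at least 20 points and 0 were lower by that much. A stretch of chromosome 2 from 98662264 to 98667326 (mm10) held 61 of them and 29727487 of their 34758560 calls in 5M-GS, at 48.5% and 86.3%, and one on chromosome 9 from 3000031 to 3038257 held 149 at 40.9% and 79.1%. A further 402 lay on chromosome 17 from 39843043 to 39848737, at 27.5% in 5M-GS and 62.9% in 60M-GS. Without the CpGs with the most calls (over 74 in either table), the levels were 74.6% and 75.8%, a difference of 1.21 points. On this basis all 20 chromosomes were higher in 60M-GS, from 0.320 points on chromosome 11 to 2.14 points on chromosome 3 among the autosomes. The X chromosome stood at 74.2% in 5M-GS and 78.5% in 60M-GS, a difference of 4.29 points.

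The difference was unevenly spread over the genome. Without the CpGs with the most calls, CpGs between genes were at 77.6% in 5M-GS and 79.6% in 60M-GS. CpGs inside genes but outside promoter windows were at 77.9% and 78.5%. CpGs in promoter windows were at 12.7% and 14.3%. Only 21448 of 34328 genes had such a window, so the other classes also hold promoters of genes without one. CpGs with 1 to 2 CpGs within 250 bp differed by 0.396 points, those with 3 to 4 by -0.0473 points, those with 5 to 9 by 0.179 points, those with 10 to 19 by 4.42 points (67.3% and 71.7%), and those with 20 or more by 2.75 points (9.75% and 12.5%). The share of CpGs under 10% methylation was 13.95% in 5M-GS and 13.1% in 60M-GS, that at 10% to 20% 1.40% and 1.00%, that at 20% to 80% 15.8% and 15.3%, that at 80% to 90% 23.6% and 26.3%, and that at 90% or more 45.3% and 44.4%.

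Some broad domains, mostly poor in CpGs, were more methylated in 60M-GS. Of 25241 windows of 100 kb, 1610 were higher in 60M-GS by at least 10 points and 0 were lower by as much. The windows that rose had a median level of 68.1% in 5M-GS and 84.4% in 60M-GS, and a median of 413 CpGs against 726 in the windows that moved by less. In the tenth of windows with the fewest CpGs, 23.6% rose and the mean level was 76.3% in 5M-GS and 82.5% in 60M-GS. In the tenth with the most CpGs, 0.318% rose. On the X chromosome 396 of 1519 windows rose, against 1214 of 23722 on the autosomes. This contrast was not matched on CpGs per window or on depth. The median number of calls per window in 5M-GS was 3850 on the X chromosome and 15398 on the autosomes. The X chromosome and the scarcity of CpGs are therefore not separate results. Adjoining windows formed 646 domains, of which 169 spanned at least 3 windows. The longest, chosen after its values were seen, ran from 120300001 to 122600000 on the X chromosome (66.2% and 83.7%) and held Pcdh11x, a protocadherin, with H2ab3 and Nap1l3. Tied for the next length were a domain on the X chromosome from 88700001 to 90800000 (68.9% and 84.9%) and one on chromosome 17 from 38100001 to 40200000. The latter held 16 protein-coding genes, among them the olfactory receptors Olfr132 to Olfr138 and exocrine peptide genes such as Esp36, and averaged 50.3% per CpG in 5M-GS and 78.2% in 60M-GS. Over all calls it stood at 31.2% and 65.6%, which includes the 402 CpGs of high depth of that chromosome. A stretch of vomeronasal receptor genes on the same chromosome, from 19600001 to 20900000, also chosen after its values were seen, stood at 58.2% and 80.7%. These windows were described without a test.

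**Figure D1:**
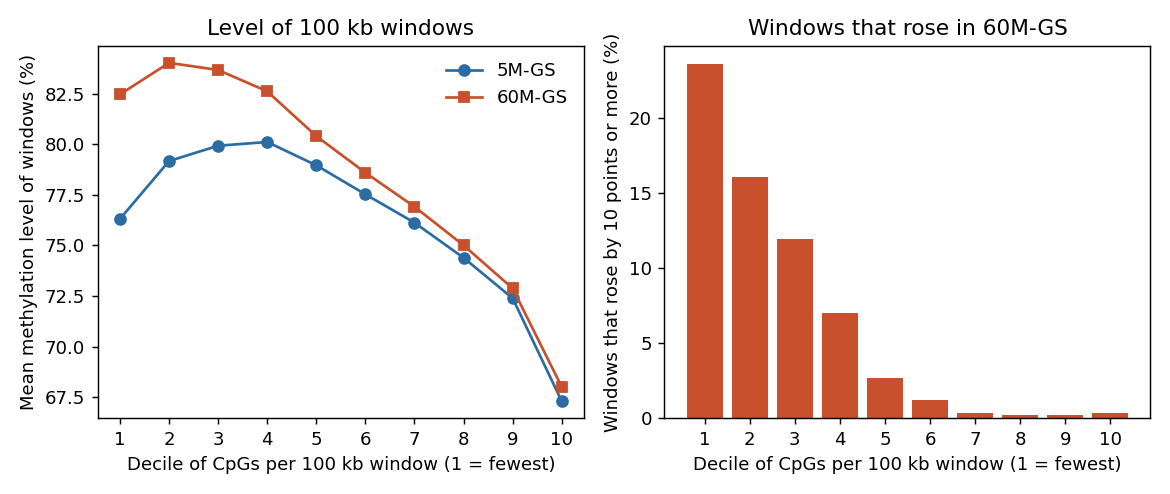
Left, mean methylation level (%) of 100 kb windows grouped into 10 equal classes by their number of CpGs, for 5M-GS and 60M-GS; right, the share of windows (%) in each class that were at least 10 points higher in 60M-GS. The share falls from 23.6% in the class with the fewest CpGs to 0.318% in the class with the most.

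At finer scale, the methylation of 1 kb tiles was compared with Fisher's exact test (two-sided, Benjamini-Hochberg adjustment) and a minimum difference of 20 points. Of 1689849 tiles, 58880 gained and 8026 lost methylation in 60M-GS. Tiles at 20% to 40% in 5M-GS gained most often, with 13791 of 41479, and 3790 of the 51383 tiles under 10% gained. The 671800 tiles above 90% in 5M-GS had a median difference of -1.89 points, and the median over all tiles was -0.452 points. These classes were formed by the 5M-GS level itself, so counting error alone would lower the highest class. Whether its fall exceeds that error was not tested. Tiles above 80% in 5M-GS cannot gain 20 points. On the X chromosome 8.93% of tiles gained, against 3.29% on the autosomes, a contrast not matched on depth or CpGs. Among tiles with at least 10 CpGs, the largest gain lay on chromosome 3 from 54633001 to 54634000, 31613 bp from the nearest annotated gene, Gm40050, with 1.58% of 1460 calls methylated in 5M-GS and 94.4% of 1754 in 60M-GS. A tile on chromosome 5 from 37807001 to 37808000, 12491 bp from the homeobox gene Msx1, stood at 2.05% and 94.3%. A tile on chromosome 9 from 91378001 to 91379000 inside Zic4, a zinc finger developmental regulator, stood at 0.860% and 92.6%. The others of the 5 largest gains were a tile on chromosome 6 from 58534001, 311 bp from Gm35077 (4.21% and 96.4%), and a tile on the X chromosome from 103227001 inside 4930519F16Rik (1.75% and 93.8%). The largest losses lay on chromosome 5 from 123258001 to 123259000 inside Wdr66 (83.1% in 5M-GS, 0.660% in 60M-GS), on the X chromosome from 99764001 (85.5% and 3.52%), on chromosome 17 from 83226001, 932 bp from Pkdcc (88.7% and 9.33%), on chromosome 10 from 58932001 inside Sh3rf3 (82.8% and 6.69%) and on chromosome 8 from 41523001 (88.6% and 14.9%). Single CpGs moved mostly the same way: of 15332174 CpGs with at least 10 calls, 309189 gained and 33028 lost, and 40285 went from at most 10% to at least 80% against 862 that went from at least 80% to at most 10%. Dividing the calls of each tile by its CpGs, which leaves about the mean depth as the number of observations and is a conservative test, left 8422 gains and 262 losses. In simulated tiles without any change but with all calls of a read identical, 50010 gains and 49176 losses were called, so a single tile near the 20 point limit is weak evidence. Both simulated libraries shared the same level in each unchanged tile, so balanced calls were fixed in advance. The simulation therefore cannot judge the excess of gains over losses in the data. The test on divided calls made 0 false calls in these simulated tiles.

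Stretches dense in CpGs, mostly unmethylated in 5M-GS, were compared in the same way. Of 23248 clusters of at least 20 CpGs, 1193 gained and 28 lost. Of the 19735 clusters under 10% in 5M-GS, 493 gained, and the median change of these 19735 was 0.051 points. Clusters at intermediate levels gained far more often: 261 of 377 at 10% to 30%, and 407 of 581 at 30% to 70%. These classes too were formed by the 5M-GS level itself, so counting error enters the contrast. Clusters centred in promoter windows gained in 74 of 10704 cases, against 829 of 9627 elsewhere in genes and 290 of 2917 between genes. The clusters outside promoter windows can include promoters of genes whose 5' end was not placed. With divided calls 702 gains and 3 losses were left. Over whole gene spans, 610 of 29889 genes gained and 23 lost. Divided calls left 36 gains and 0 losses, a count set largely by the divisor, since no read covers a whole gene.

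Promoter windows, from 1000 bp upstream to 500 bp downstream of the inferred 5' end, were then compared gene by gene. Of 21076 windows, 842 gained and 70 lost methylation in 60M-GS, and among protein-coding genes 392 of 14784 gained and 27 lost. Of the 12754 windows under 10% in 5M-GS, 85 gained, and the median change over all windows was 0.222 points. Divided calls left 250 gains and 4 losses, under a test that recovered 0 of 50 simulated changes of 25 points. With no change but with all calls of a read identical, 354 gains and 337 losses were called in simulated windows, of which 4 exceeded 50 points, whereas 239 gains and 4 losses exceeded 50 points in the data. The 5' end was taken as the CpG-dense end of each gene. This rule was right for 94.1% of the 102 genes of known strand it could place, which also served to choose it. The windows of the remaining share of genes, which can exceed the number of called genes, may lie at the other end. For other genes the rule may be right less often.

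Among protein-coding genes, leaving out predicted and clone-named ones, the promoter with the largest gain was that of Taf7l2. This gene, a retrogene relative of the transcription factor subunit TAF7L, was at 5.26% in 5M-GS and 93.1% in 60M-GS (difference 87.9 points, interval 86.1 to 89.4, 1655 and 1587 calls, window on chromosome 10 from 116113417). Adad2, an RNA-binding gene of spermatogenesis, was at 5.18% and 83.3%, Gpat2, an acyltransferase of the germline piRNA pathway, at 12.8% and 88.5%, and Btbd18, a regulator of piRNA precursor transcription, at 11.6% and 85.8%. Mcts2, an imprinted retrogene inside H13, was at 5.17% and 92.1%. Gains also fell on the bile acid receptor Nr1h4 (13.8% and 88.3%), the Bcl2 family member Bcl2l10 (12.2% and 90%) and the Schlafen gene Slfn4 (12.9% and 90.2%). Further large gains were on Cldn34b1 (6.67% and 89.5%), the olfactory receptor Olfr658 (9.40% and 89.4%) and Fam228a (15.1% and 89.4%). All of these gains also passed the test on divided calls.

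**Figure D2:**
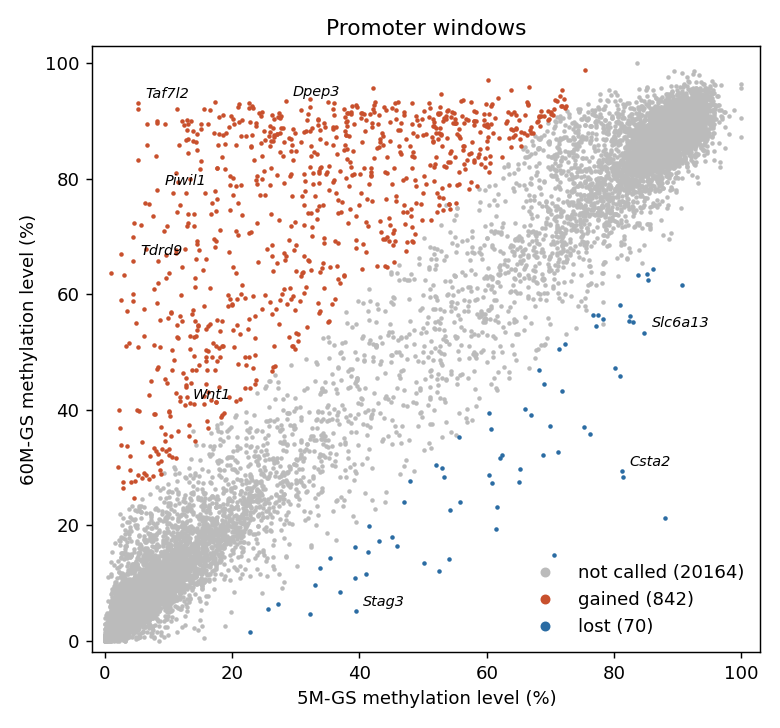
Methylation level (%) of each of 21076 promoter windows in 5M-GS (horizontal axis) and 60M-GS (vertical axis), coloured by the Fisher's exact test call. Gains (842) outnumber losses (70), and Taf7l2, Piwil1, Tdrd9, Dpep3, Wnt1, Stag3, Csta2 and Slc6a13 are marked.

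The largest losses were smaller. Csta2, a cystatin gene in a cluster of close paralogs, was at 81.2% in 5M-GS and 29.3% in 60M-GS (a difference of -51.9 points, interval -56.8 to -46.5). Stag3, the cohesin subunit of meiosis, was at 39.4% and 5.07% (difference -34.4 points, interval -39.2 to -29.4, Fisher's exact test, adjusted p = 1.70e-36). The microglial gene Tmem119 was at 61.4% and 19.3%, the muscle gene Txlnb at 71.2% and 32.7%, and the myeloid receptor Treml4 at 61.6% and 23.1%. The sodium-dependent transporter Slc5a11 was at 75.3% and 36.9%. The 5' ends of all 12 losses were inferred from CpG density, and that of Slc5a11 is in doubt. The others were Osbpl7 (50.1% and 13.4%), A2ml1 (80.9% and 45.8%), Lrtm1 (54.2% and 22.6%), the GABA transporter Slc6a13 (84.8% and 53.3%), Abca9 (40.9% and 11.5%) and the phosphatase subunit Ppp2r2b (36.9% and 8.39%). From 2000 bp upstream to 1000 bp downstream, 4 of the 12 losses were under the limit, at -9.80 points for Txlnb, -10.8 for Lrtm1, -18.5 for Treml4 and -15.9 for Ppp2r2b. Some that stayed over it also shrank, to -21.1 points for Stag3, -24.5 for Slc5a11 and -25.0 for Tmem119. Csta2 also passed the test on divided calls, which has little power for differences of the size of the other 11. Stag3 did not pass it (Fisher's exact test on divided calls, adjusted p = 0.46). In simulated windows without change but with all calls of a read identical, 337 losses were called, against 70 in the data. A loss that did not pass on divided calls may therefore be a false call.

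**Figure D3:**
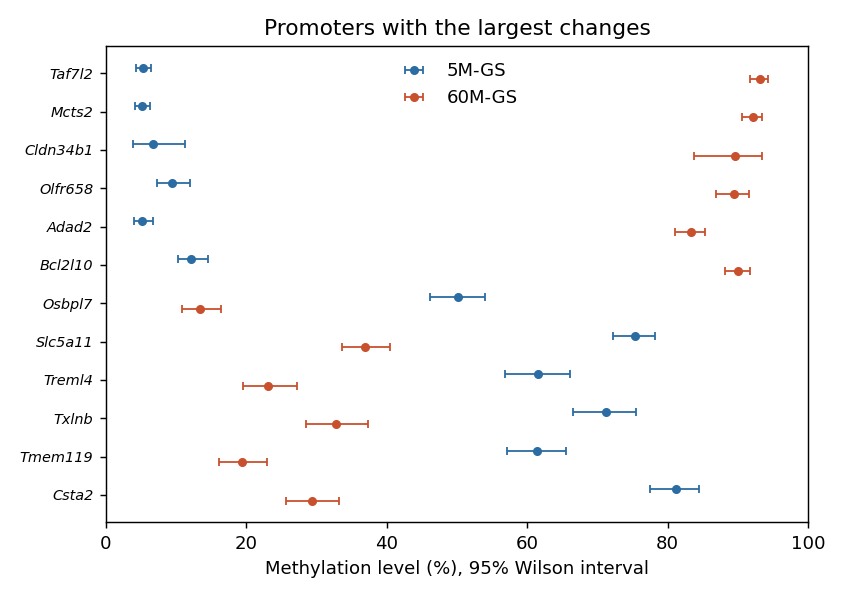
Methylation level (%) with its 95% Wilson interval of the 6 promoters with the largest gain and the 6 with the largest loss, in 5M-GS and 60M-GS. Taf7l2 runs from 5.26% to 93.1% at the top, and Csta2 from 81.2% to 29.3% at the bottom.

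The series title names Wnt7b, a secreted Wnt ligand, and JNK, the stress kinase encoded by Mapk8, Mapk9 and Mapk10 that phosphorylates the transcription factor Jun. None of their promoter windows passed the test. Wnt7b was at 0.380% in 5M-GS and 0.310% in 60M-GS (difference -0.0700 points, interval -0.470 to 0.340, Fisher's exact test, adjusted p = 0.949, 2112 and 1936 calls). Mapk8 was at 1.51% and 1.78%, Mapk9 at 0.550% and 1.10%, and Jun at 0.540% and 0.490%. The Mapk10 window, at the outermost annotated end of a gene with several promoters, was at 88.9% and 93.4% (Fisher's exact test, adjusted p = 0.0811). Of 69 tested Wnt pathway genes, 2 gained and 0 lost, also when adjusted over the list alone. The share that gained, 2.9%, was near the 2.65% of all protein-coding windows. These were the ligands Wnt1 (12.6% and 40.9%) and Wnt10a (5.18% and 28.6%). The Wnt10a difference was 18.1 points, under the limit, with a window from 2000 bp upstream to 1000 bp downstream, and it did not pass the test on divided calls. Of 40 JNK pathway genes, 0 gained or lost by either adjustment.

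Among 41 promoters of meiosis and germline-defence genes, 5 gained and 1 lost, both over all genes and adjusted over the list alone. The share that gained was 12.2%, against 2.65% of all protein-coding windows. That contrast was not tested or matched on 5M-GS level. The gains were on Piwil1, a piRNA-binding Argonaute of meiotic cells (8.23% and 78.0%), Tdrd9, a helicase of the piRNA pathway (4.39% and 65.8%), Dpep3, a testis dipeptidase (28.4% and 93.4%), Tex19.1, a germ cell repressor of retrotransposons (34.4% and 89.6%), and Tex12, of the synaptonemal complex (6.39% and 28.7%). The loss was on Stag3, which did not pass the test on divided calls. The list's median difference, 0.635 points, stood at the 55.7th percentile of 10000 random lists matched on level and number of CpGs. A median over 41 promoters hardly registers 5 large gains. Of 12 spermatid genes, 1 gained, Odf1 of the sperm tail (23.7% and 79.9%), whose 5' end was inferred from CpG density and is in doubt. Of 30 spermatogonial stem cell genes, 1 gained, Shisa6 (43.2% and 72.6%). That list's median difference, -0.0810 points, stood at the 0.490th percentile of matched random lists, and its median over gene spans, 0.161 points, at the 32.0th. In all, 21 lists were ranked, with no allowance for their number. None of 13 spermatogonial differentiation genes and none of 16 pluripotency genes was called, the latter list standing at the 95.1st percentile.

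Against 842 of 21076 promoter windows in all, some families in tandem clusters held the following gains, a contrast in frequency that was not tested. The share that gained depended on the 5M-GS level: 85 of 12754 windows under 10%, 314 of 1973 at 10% to 30%, 429 of 1311 at 30% to 70% and 14 of 5038 above. In the last class, windows above 80% cannot gain 20 points. The median 5M-GS level was 15.4% for the protocadherin list, 81.7% for the olfactory and vomeronasal list and 7.21% for the Rhox list. The contrast was not matched on this level. Of 26 clustered protocadherin genes, which encode neuronal adhesion proteins, 5 gained and 0 lost, with a median difference of 5.84 points above 99.89% of 10000 matched random lists. Examples were Pcdhb15 (14.4% and 86.3%), Pcdha8 (33.4% and 90.3%), Pcdhb14 (38.1% and 89.1%) and Pcdhb11 (32.2% and 82.0%), the other gain being Pcdhb10. Over gene spans, 24 of 57 protocadherins gained. Of 1785 olfactory and vomeronasal receptor genes, only 126 had a tested window under the 5' end rule, and of these 20 gained and 0 lost (median difference 2.75 points, above 99.99% of the matched lists), among them Olfr658, Olfr212 (38.1% and 91.4%), Olfr976 (35.9% and 88.9%) and Olfr1361 (25.1% and 77.1%). Of 48 Rhox and other X-linked reproductive genes, 8 gained and 0 lost, with a median difference of 1.34 points at the 92.5th percentile. Examples were Magea3 (16.3% and 89.5%), Rhox7a (22.9% and 85.6%), Magea5 (14.1% and 61.2%) and Rhox3f (45.8% and 91.9%, a difference of 22.5 points with a minimum of 10 calls). The counts of these 3 lists were the same adjusted over the list alone. Members of these families resemble each other in sequence, so reads may be shared between copies. Many also lie side by side and may change together, while the random lists were not matched on position. The percentiles may therefore overstate how rare these medians are.

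Developmental regulators were mostly left at low levels. Of 104 developmental transcription factor genes outside the Hox clusters, 3 gained, Sox30 (56.4% and 89.7%), Evx2 (8.29% and 32.3%) and Olig3 (9.62% and 32.9%). The Olig3 difference was under the limit from 2000 bp upstream to 1000 bp downstream (12.01 points) and as the mean of per-CpG levels (19.7 points). Of the tested zinc finger genes, 4 gained and 341 were not called. The 4 were Zscan5b (16.6% and 61.1%), Zfp985 (29.9% and 72.5%), Zfp474 (36.3% and 77.5%) and Zfp575 (29.9% and 57.2%). Of 25 glycolysis genes, 1 gained, the pyruvate kinase gene Pklr (20.3% and 50.8%). Its 5' end was inferred from CpG density and is in doubt, and the difference was 11.5 points, under the limit, from 2000 bp upstream to 1000 bp downstream. None of 29 mitochondrial biogenesis and antioxidant genes, none of 36 senescence and telomere genes and none of 24 DNA methylation machinery genes was called. The median difference of the senescence and telomere list, -0.0280 points, stood at the 1.59th percentile, and its median over gene spans, 0.739 points, at the 85.2nd. Of the machinery genes, Dnmt3b was at 0.95% and 1.36%, Tet1 at 8.26% and 10.8%, Tet2 at 0.40% and 0.10%, and Tet3 at 10.8% and 11.1%. The Dnmt3l window was at 74.9% and 63.4% (Fisher's exact test, adjusted p = 4.13e-04, under the 20 point limit). The windows of Dnmt1 (94.3% and 92.1%, but a difference of 8.35 points from 2000 bp upstream to 1000 bp downstream) and Dnmt3a (82.8% and 84.6%) lay at the outermost annotated ends of these genes, and Dnmt3c had no tested window. Of the markers of other cell types, 1 of 19 fibroblast genes gained (Postn, 39.2% and 80.8%), 1 of 14 Sertoli and Leydig genes (Lhcgr, 48.2% and 93.2%) and 1 of 8 blood and endothelial genes (Cd3e, 50% and 77.5%), and 0 lost.

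Imprinted regions were compared as a separate list, since male germ cells carry paternal imprints and somatic cells carry 1 methylated and 1 unmethylated copy. Of 23 tested windows, 2 gained and 0 lost, with p-values adjusted over the list alone. The Mcts2 window on chromosome 2 from 152686148 to 152687648 rose by 86.9 points (interval 85 to 88.5), and the Gnas window on chromosome 2 from 174283320 to 174284820 was at 8.26% in 5M-GS and 58.5% in 60M-GS. From 2000 bp upstream to 1000 bp downstream, the differences were 69.1 points for Mcts2 and 27.2 points for Gnas. Of the 20 windows at maternally methylated genes, 13 were under 12% in both, including Peg3 (0.95% in both), Kcnq1ot1 (9.50% and 9.64%), Airn (8.10% and 7.89%), Mest (5.68% and 5.41%), Peg10 (2.13% and 0.590%), Plagl1 (1.76% and 1.18%), Nnat (5.53% and 5.21%), Zrsr1 (5.08% and 3.12%), Peg13 (1.20% and 0.740%), Slc38a4 (1.67% and 0.710%), Grb10 (0.530% and 0.540%), Nap1l5 (7.89% and 10.96%) and Herc3 (0.780% and 1.28%). The paternally methylated regions upstream of H19 (93.5% and 91.0%), Meg3 (93.5% and 92.1%) and Rasgrf1 (91.1% and 92.1%) were high in both. Inpp5f was at 18.8% and 19.6%, Cdh15 at 34.1% and 30.3%, Fkbp6 at 44.1% and 25.8%, Snrpn at 41.5% and 55.6%, and Impact at 85.7% and 87.2%. The Snrpn and Impact windows hold 6 and 13 CpGs at outermost annotated ends. The Gnas window also lies at the outermost annotated end of its gene. Each listing as maternally methylated was made for the gene and need not hold for its window, at Gnas or among the 13 low ones. A low window that misses the imprinted region says nothing about the imprint. A window at Snurf, added after the data were seen, was at 1.90% and 0.350%. Of 48 imprinted genes, 3 promoters gained, the last being Slc22a2 (52.0% and 88.8%), at 17.6 points from 2000 bp upstream to 1000 bp downstream.

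**Figure D4:**
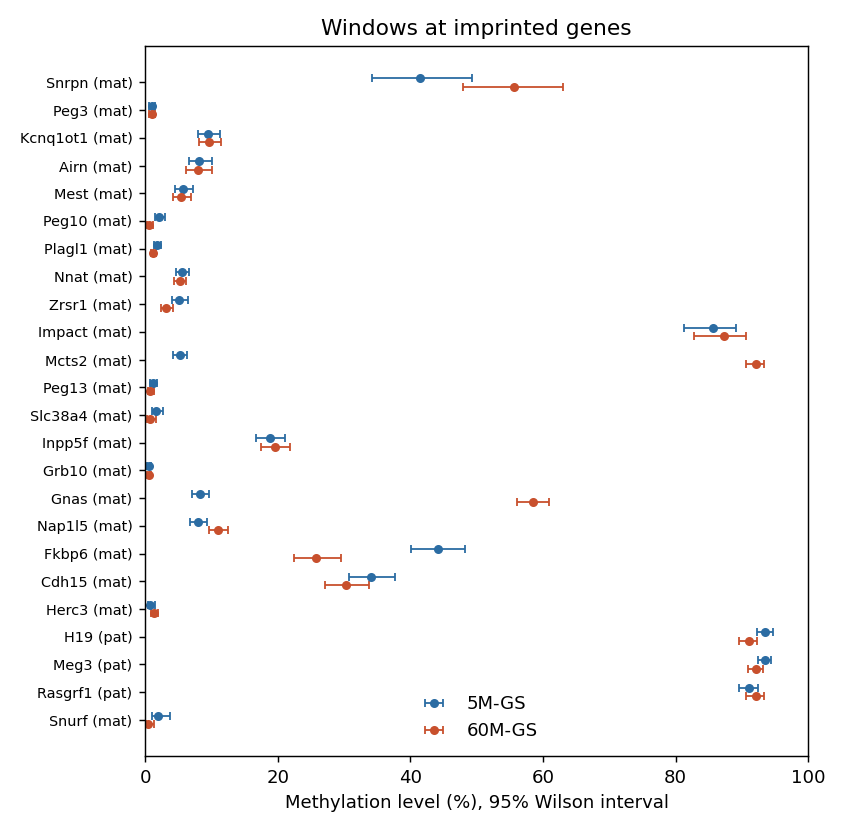
Methylation level (%) with its 95% Wilson interval of the windows at imprinted genes in 5M-GS and 60M-GS. The labels mat and pat give the class under which each gene was listed, and a window need not lie at the imprinted region itself. Mcts2 (5.17% and 92.1%) and Gnas (8.26% and 58.5%) stand apart, while H19, Meg3 and Rasgrf1 are above 90% in both.

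The calls per CpG were compared along the chromosomes as well, on CpGs under the upper limit of calls. Relative to the median autosome, chromosome 15 stood at 1.26 in 5M-GS and 1.02 in 60M-GS, and chromosome 16 at 1.12 and 1.00. The 60M-GS over 5M-GS ratio was 0.812 for chromosome 15, 0.892 for chromosome 16 and 0.975 for chromosome 17, against 1.0005 to 1.0091 for the other 17 chromosomes. The X chromosome stood at 0.459 and 0.462. The ratio was described without a test.

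**Figure D5:**
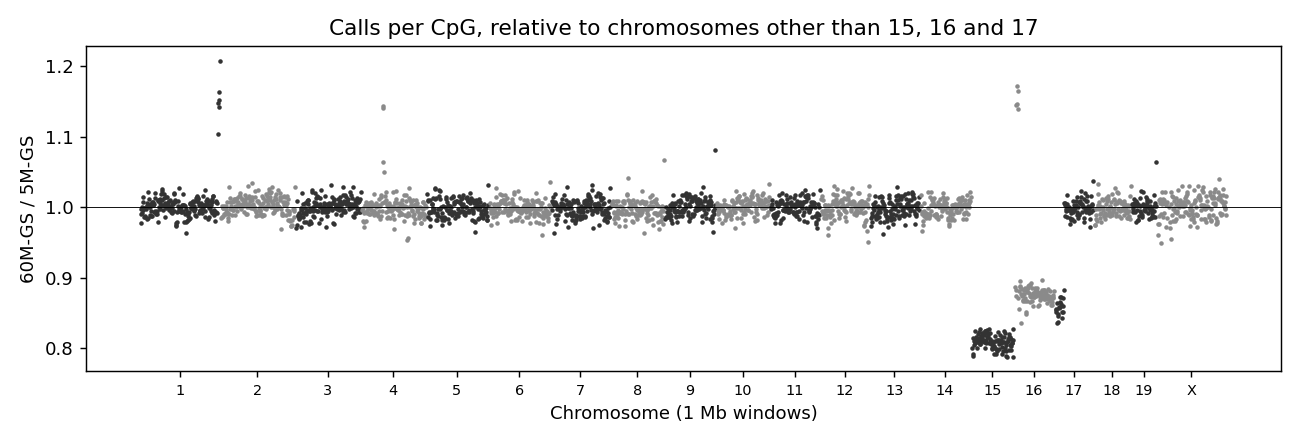
Calls per CpG of 60M-GS over 5M-GS in 1 Mb windows along the chromosomes, each library scaled to the chromosomes other than 15, 16 and 17. All 101 windows of chromosome 15 lie between 0.788 and 0.828.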

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

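All tests in this part were chosen after the result was seen.

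Sequencing depth differed between the cultures on a few chromosomes, a signal outside the methylation levels. The 60M-GS over 5M-GS ratio of calls per CpG was 0.81 over chromosome 15 from 3000001 to 104000000, 0.882 over chromosome 16 from 3000001 to 6000000, 0.875 over chromosome 16 from 11000001 to 98000000, and 0.857 over chromosome 17 from 3000001 to 24000000. It was 1.146 over chromosome 16 from 6000001 to 11000000, 1.149 over chromosome 1 from 190000001 to 196000000, and 1.142 over chromosome 4 from 53000001 to 55000000. Of the 1 Mb windows of all chromosomes other than 15, 16 and 17, the middle 98% lay between 0.971 and 1.03. Chromosome 15 stood at 1.23 times the other chromosomes in 5M-GS and at 0.997 in 60M-GS, and the piece of chromosome 16 from 6000001 to 11000000 at 1.23 and 1.44.

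A bias by CpG density would bring the chromosome 15 ratio close to 1 in some density class, but the class nearest to 1 gave 0.8102. Mapping trouble at part of chromosome 15 would leave other windows of it in the usual range, and 0 of its 101 windows were there. This outcome was known beforehand, since the flagged stretch spans all 101 windows. A difference in copy number between the cultures, such as an additional chromosome 15 in part of the 5M-GS cells, may explain the pattern. That all 101 windows departed the same way restates the flagged result and gives no separate support. The pieces of chromosome 16 departed in both directions, at ratios of 0.882, 1.146 and 0.875, and were not weighed. A difference in copy number remains a hypothesis, found and tested on the same data. Whether the replicates share it could not be seen in pooled tables, and culture age stays among the open explanations, as untested.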

How the results depend on the processing

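No paired analysis was possible because the tables pool both replicates of each culture age and carry no replicate column; for the same reason no replicate could be left out. CpG islands by sequence were not run. Where a value below has no stated reason, the cause was not tested. The alternatives chosen after seeing the data were CpG-dense clusters, the limit of 1000 calls, the minimum of 50 points, the stricter 5' end rule, both gene ends, gene spans for lists, and leaving out chromosomes 15, 16 and 17. Depth limits the X chromosome most, with a median of 73 calls per tile in 5M-GS against 187 on autosomes.

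The genome-wide difference of 3.96 points kept its direction in every alternative, at 3.94 with a minimum of 1 call, 4.06 with 10, 1.31 as the mean of per-CpG levels, 1.21 without the deepest CpGs and 1.24 with at most 1000 calls. The drop comes from the deepest CpGs, which these alternatives leave out or weigh less. Promoter windows gave 2.00 points with a minimum of 10 calls, 1.59 without the deepest CpGs and 1.38 as the mean. Gene spans gave 1.10, 0.595 and 0.579 in the same order. CpGs between genes gave 7.67 with a minimum of 1 call, 7.98 with 10, 2.05 without the deepest CpGs and 2.27 as the mean.

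Changed tiles (66906) numbered 120662 at 10 points (92557 gained, 28105 lost), 36439 at 30 points, 10482 at 50 points, 8684 with calls divided by the CpGs of the region (divided calls) and 43160 with at least 8 CpGs. Changed promoters (912) numbered 1689 at 10 points, 243 at 50 points, 254 with divided calls, 569 with the stricter 5' end rule and 2113 genes with either end. Changed gene spans (633) numbered 1905 at 10 points, 259 at 30 points and 36 with divided calls. Changed clusters (1221) numbered 582 at 50 points, 705 with divided calls and 5966 with at least 10 CpGs. Stricter limits and fewer regions lower such counts by construction. Gains outnumbered losses in each of these alternatives, in the 100 kb windows and in single CpGs.

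With gene spans in place of promoter windows, called genes numbered 0 for the spermatogonial stem cell list, 1 for meiosis and germline defence (Tex12), 2 for pluripotency (Klf4 and Klf2), 1 for Wnt (Fzd5), 2 for glycolysis (Pgam2 and Eno2), 1 for DNA methylation machinery (Mbd3), 2 for Hox (Hoxc13 and Hoxc8), 10 for developmental transcription factors, 24 for protocadherins, 49 for olfactory and vomeronasal receptors, 14 for zinc fingers, 0 for fibroblast markers and 0 for blood and endothelial markers. For Sertoli and Leydig markers 1 span (Rhox5) was lost where 1 promoter (Lhcgr) had gained, a reversal. Glycolysis genes gave 2 calls with windows of 500 bp on each side. Of the imprinted regions, 4 were called at 10 points, and the mean of per-CpG levels gave 2 gained and 1 lost, the loss being Fkbp6 (-23.0 points).

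Of 69 named promoters, 69 kept their call or lack of one with a minimum of 1 or 10 calls, without the deepest CpGs, after thinning and with 500 bp on each side. With divided calls 30 no longer passed the test at unchanged differences. For these, the low power of that test could not be told apart from false calls of the main test. With 2000 bp upstream and 1000 bp downstream 8 lost their call, and with the mean of per-CpG levels 1 (Olig3). No called promoter among the 69 changed sign. Among those not called, the Dnmt1 difference turned from -2.24 to 8.35 points with 2000 bp upstream and 1000 bp downstream, and small differences of Dnmt3b, Tet1, Tet3, Mapk8, Mapk9 and Wnt7b changed sign in 1 or more alternatives.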

Other observations

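The following domains that rose in 60M-GS were picked after their values were seen, among long domains of which some held other genes and some no protein-coding gene. The Obox homeobox genes on chromosome 7 from 14600001 to 15800000 stood at 59.7% in 5M-GS and 78.5% in 60M-GS. The Pate genes and Acrv1, of the epididymis and the acrosome, on chromosome 9 from 35600001 to 36700000 stood at 55.6% and 76.4%. The Klra genes, killer cell receptors, on chromosome 6 from 130300001 to 131200000 stood at 49.5% and 77.8%, and the Samt genes on the X chromosome from 153900001 to 154800000, expressed in spermatids, at 58.9% and 81.4%. Over gene spans, 6 of 71 Rhox and other X-linked reproductive genes gained and 1 lost, the loss being Rhox5. Among 135 developmental transcription factor genes, 10 spans gained, including Neurod6, Dlx4, Foxh1 and Sox8, and among imprinted genes Magel2 and Zim1 gained. Promoter windows of lncRNA genes gained in 450 of 6292 cases.

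All tests below were chosen after the result was seen.

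The 842 CpGs with over 1000 calls rose from 46.8% to 85% over all their calls. Incomplete bisulfite conversion in 60M-GS would raise unmethylated clusters as well, but clusters under 10% in 5M-GS had a median change of 0.051 points. DNA of somatic feeder cells in 5M-GS would bring imprinted regions towards intermediate levels. The median of the 20 windows at maternally methylated genes was 5.6% in 5M-GS. Inpp5f (18.8%), Cdh15 (34.1%), Snrpn (41.5%) and Fkbp6 (44.1%) were at intermediate levels, and Impact was at 85.7%. The windows need not cover the imprinted region, so the low median argues against much feeder DNA only for windows that do. Additional methylated repeat copies collected in 60M-GS, beside the unmethylated ones, would raise the share of calls on these CpGs, but it was 7.53% in 5M-GS and 6.891% in 60M-GS. An exchange of unmethylated for methylated copies among the reads collected at these positions was not tested and stays open.

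The 100 kb windows poor in CpGs rose most often. Chance from low depth would make windows fall as often as rise, yet 0 fell by 10 points. The depth difference of chromosomes 15, 16 and 17 would place most risen windows there, yet 8.13% of them were on these chromosomes. Culture age and other differences between the cultures, and the spread between replicates, were not tested.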
